A study of Mus musculus with 6 samples.

How the data were processed

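The measurements are RNA-seq read counts of primary hepatic stellate cells of mice (genotype BucheKI/KI-Hep, CCl4-treated), in 3 libraries labelled PBS and 3 labelled DOX. RNA was extracted with an RNeasy kit and libraries were built from total RNA with a SMARTER mRNA-Seq kit, per the labels' protocols. Whether counting used the strand, and how reads matching several genes were treated, are not given in the sources used here, nor are the aligner and the counting tool. The genome builds GRCm38, mm10 and hg38 are named with no role, per the submitters' processing notes. The authors deposited a table of raw counts for 22905 gene symbols, 1 column per sample with no pooling of replicates, and a table of FPKM values for the same genes. Each nonzero deposited FPKM value equalled the count per kilobase of a fixed gene length and per unit of its library total (the usual FPKM scale), within a relative tolerance of 0.0001 (100% of values), so the FPKM table is the same measurement on another scale. No column of per-sample values was left unmatched to a sample.

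Groups and replicate numbers were taken from the sample titles. Before averaging, replicates of a group were compared by a chi-square test of their counts. The statistic per degree of freedom was between 41.5 and 89.0 for the 6 pairs within groups, so no library was a repeat of another. Counts totalled 36220282 to 37707364 per library. Counts of 3 reads, the upper limit that a count of 0 allows, corresponded to 0.0758 to 0.0878 CPM, which covers counting error only.

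The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on the deposited counts, with TMM factors, group as the only term, all 6 libraries in the fit and filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 14439 genes. The test was two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. All adjusted p of genes in the results come from this fit unless another tool is named. The common biological coefficient of variation was 0.230, and TMM factors were between 1.02 and 1.06 in PBS and between 0.923 and 1.01 in DOX. CPM values use the TMM-scaled library size. The SE of a log2 fold change was derived from its F statistic, and values after ± are standard deviations of 3 libraries.

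Before the data were examined, 44 gene lists were fixed, covering stellate cell states, matrix, signalling, inflammation, stress, metabolism and markers of other liver cell types. For each list, members past the threshold were counted over all genes and with p adjusted over the list alone. Lists with at least 5 tested members (43 lists) were also tested by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and by fry. Scores of marker lists are means of log2 CPM (prior count 2) less the PBS mean. The 13 mitochondrially encoded genes were matched to the names the count table uses. Coordinates come from the RefSeq annotation of GRCm38, in which 21844 of the symbols (95.4%) were found.

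The rule for named genes was also fixed beforehand. It took Bche, Ache and the muscarinic receptor genes Chrm1, Chrm2, Chrm3, Chrm4 and Chrm5, and the core activation panel of Acta2, Col1a1, Col1a2, Col3a1, Timp1, Tgfb1, Pdgfrb, Des and Lrat. It took the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a predicted or clone name. From each list described it took up to 4 members with the lowest p in the leading direction, and the 2 most abundant members of each list of another cell type. Genes outside the rule are marked where they are named.

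The code was tested on simulated counts drawn from the real means and library sizes of this comparison, with 14439 genes, of which 100 were changed by each of 2 fold sizes. The edgeR test recovered 74 of 100 genes with a log2 fold change of 1 and 95 of 100 with 2, and 8.15% of its calls were false. DESeq2 recovered 90 and 96 of 100 with 24.7% false calls, limma-voom 73 and 95 with 6.67%, and limma on log2(FPKM + 1) 39 and 92 with 2.24%. With no gene changed, edgeR called 0 genes and camera 1 of 43 lists. The simulated genes were drawn independently of each other. The camera count therefore does not cover lists whose members move together, such as the interferon list, with an estimated correlation of 0.825.

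Alternatives fixed before the data were examined were RLE and upper-quartile factors, library totals alone, no low-count filter, a filter of 5 CPM in 3 samples, DESeq2 1.42.0 with its own size factors, limma-voom, a robust quasi-likelihood fit, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a filter of 1 FPKM in 3 samples, removal of genes of other cell types' lists, a fold threshold, and leaving out each library in turn. Added after the data were seen were a macrophage marker score and a hepatocyte marker score as covariates (each the mean log2 CPM of its list), removal of each library's trend with gene length (loess, span 0.5) and list counts without DOX replicate 3.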

Results

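RNA of primary mouse hepatic stellate cells was sequenced in 6 libraries. Stellate cells are the vitamin A storing pericytes of the liver, and on injury they turn into matrix-producing myofibroblasts. The animals carried the genotype named BucheKI/KI-Hep and had been treated with CCl4 (carbon tetrachloride), a hepatotoxin used to model liver fibrosis. There were 3 libraries labelled PBS and 3 labelled DOX. The series describes over-expression of butyrylcholinesterase in hepatocytes before stellate cells were isolated, and its title names stellate cell activation and paracrine muscarinic signalling. The comparison of DOX with PBS therefore asks how transcripts of the isolated cells differed after hepatocyte butyrylcholinesterase was raised in CCl4-treated animals. How pure the isolated stellate cells were could not be settled from the sources used here, and endothelial and macrophage transcripts were abundant in both groups, so the values are those of the whole RNA of each library and cannot be assigned to stellate cells alone. DOX without the introduced gene and animals without CCl4 were not analysed here. An action of DOX itself therefore cannot be told apart from that of the introduced gene. Total counts per library were between 36220282 and 37707364, so that 1 read was worth between 0.0253 and 0.0293 CPM (counts scaled to library size). Nothing in the labels says that the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The first principal component held 50.9% of the variance and separated the groups, with PBS libraries between -43.8 and -32.2 and DOX libraries between 21.4 and 51.6.

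Bche transcripts, the target of the manipulation, were 121-fold higher in the DOX libraries than in the PBS libraries. The counts were 8, 26 and 14 in PBS replicates 1, 2 and 3 and 1225, 582 and 3639 in DOX replicates 1, 2 and 3. As normalised counts this was 0.415 ± 0.240 CPM in PBS and 50.5 ± 43.4 CPM in DOX (SD, n = 3 each). The log2 fold change was 6.91 (SE 0.85, edgeR quasi-likelihood adjusted p = 0.0206). Bche encodes an enzyme that hydrolyses acetylcholine and other choline esters, and the gene lies on chromosome 3 from 73635805 to 73708436 in GRCm38. Hepatocyte transcripts differed between the DOX libraries in the same order as Bche. Alb, which encodes albumin, stood at 346, 116 and 1862 CPM in DOX replicates 1, 2 and 3 and at 85.4, 166 and 209 CPM in PBS replicates 1, 2 and 3. For every 100 normalised Alb counts there were 10.3, 14.2 and 5.33 of Bche in DOX replicates 1, 2 and 3, against 0.248, 0.409 and 0.170 in PBS. The Bche call was lost without PBS replicate 2 (log2 fold change 7.45, edgeR adjusted p = 0.0694), without PBS replicate 3 (6.81, edgeR adjusted p = 0.0845) and in limma-voom (6.66, adjusted p = 0.0697), and the log2 fold change was 5.96 without DOX replicate 3. The sources used here do not say whether reads of the introduced sequence were counted under this symbol.

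**Figure D1:**
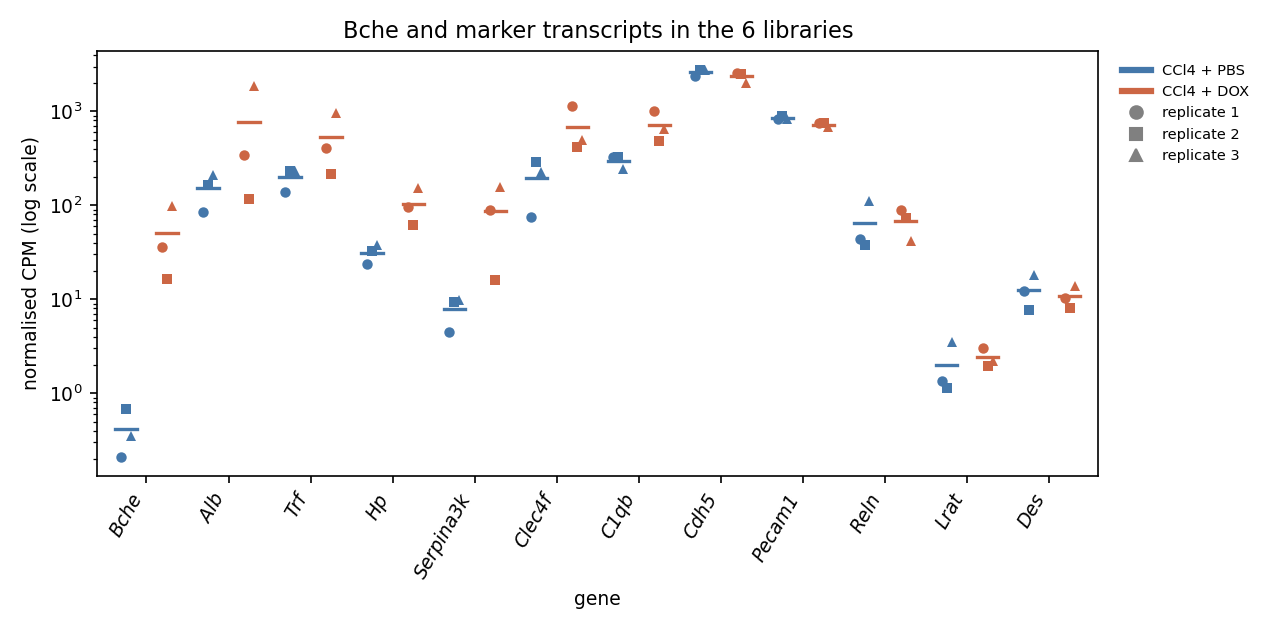
Normalised CPM on a log scale for Bche and 11 marker genes in the 6 libraries, with each point a library and each bar the mean of 3. Bche lay between 0.212 and 0.680 CPM in PBS and between 16.4 and 99.3 CPM in DOX, and Alb was highest in DOX replicate 3 at 1862 CPM.

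Of the other cholinergic genes, Lynx1, a modulator of nicotinic receptors, rose from 1.19 ± 0.371 to 3.84 ± 0.571 CPM (SD, n = 3 each), a log2 fold change of 1.69 (SE 0.30, edgeR adjusted p = 0.0299). Slc44a1, a choline transporter, rose 1.39-fold from 120 to 166 CPM (edgeR adjusted p = 0.0417). Together with Bche these were the 3 of 9 tested members of the cholinergic list that passed, and 5 passed when adjusted over the list alone. Ache, the acetylcholinesterase gene, had 0.508 ± 0.173 CPM in PBS and 0.415 ± 0.118 CPM in DOX (log2 fold change -0.29, SE 0.41, edgeR adjusted p = 0.678). Muscarinic receptor transcripts were near the limit of this depth. Chrm4 had 0.183 ± 0.0973 CPM in PBS and 0.508 ± 0.0987 CPM in DOX (edgeR adjusted p = 0.113). Chrm2 had 0, 1 and 2 counts in PBS and 0, 0 and 1 in DOX, and Chrm3 had 2, 1 and 2 counts in PBS and 1, 0 and 10 in DOX, so neither was tested. Chrm1 and Chrm5 were not analysed here.

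Across the transcriptome, Saa2, Ubd, Slc16a3 and Ccl12 were among the genes that rose in the DOX libraries, while Ptx3, Mmp10, Star and other genes fell by smaller factors. Of 14439 genes tested, 926 passed an adjusted p of 0.05, with 632 higher and 294 lower in DOX. The changes upward were larger, with a median log2 fold change of 1.38 against -0.63 for the genes that fell, and 434 of the higher and 50 of the lower genes changed at least 2-fold. The libraries of the groups did not overlap for 4995 genes, 34.6% of those tested, where chance gives 10%. The split between higher and lower calls depended on scaling. By library totals alone, 611 genes were higher and 730 lower, 45.6% higher in place of 68.3%, with the median of all genes shifted by -0.13. By limma on log2(FPKM + 1), which also changes the test, the unit and the pseudocount, 423 were higher and 402 lower. No gene passed without PBS replicate 2 (smallest edgeR adjusted p = 0.0663, 3294 genes at an unadjusted p under 0.05) or without PBS replicate 3 (0.0634, 3092 genes), and 85 and 438 passed without DOX replicates 1 and 2. Of the 96 called genes that are named, 38 lost the call without PBS replicate 1, 78 without DOX replicate 1, 47 without DOX replicate 2 and 21 without DOX replicate 3. With the macrophage marker score as a covariate, a setting chosen after the data were seen, edgeR called 0 genes (652 at an unadjusted p under 0.05), and with the hepatocyte marker score 1 gene, Bche (2533 genes). The macrophage score overlapped with the groups (r = 0.886 over the 6 libraries), so the loss of calls does not show what caused the changes.

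The 8 genes taken by the naming rule for the highest fold changes, at a mean of at least 5 CPM, were Bche, Saa2, Ubd, Saa1, Slc16a3, Ccl12, Arg1 and Gzmb. Saa2 and Saa1 encode serum amyloid A acute-phase proteins. Saa2 rose from 0.225 ± 0.200 to 13.2 ± 9.89 CPM (log2 fold change 5.85, SE 0.93, edgeR adjusted p = 0.0272) and Saa1 by a log2 fold change of 4.89 (SE 0.82, edgeR adjusted p = 0.0284). These paralogs are near-identical, so reads may have been split between them. Ubd, a ubiquitin-like modifier induced by inflammatory cytokines, rose 32.3-fold from 1.57 ± 1.47 to 50.6 ± 36.2 CPM (edgeR adjusted p = 0.0311), with 54.0, 85.1 and 12.8 CPM in DOX replicates 1, 2 and 3. Its log2 fold change of 5.02 was 6.13 without PBS replicate 1 and 4.41 without DOX replicate 2, and its call was lost in 7 of 20 alternative settings, among them limma-voom and leaving out PBS replicate 2 or 3 or DOX replicate 1 or 2. Slc16a3, a lactate exporter, rose 28.9-fold from 3.68 ± 1.13 to 106 ± 70.7 CPM (edgeR adjusted p = 0.0215). The chemokine gene Ccl12 rose 20.1-fold, Arg1, which encodes arginase, 17.0-fold, and Gzmb, which encodes granzyme B of cytotoxic lymphocytes, 16.9-fold (edgeR adjusted p = 0.0233, 0.0206 and 0.0256). Single libraries also moved the log2 fold changes of Saa2 (6.78 without PBS replicate 2 and 5.17 without DOX replicate 3), Saa1 (4.10 without DOX replicate 3), Ccl12 and Arg1 (3.57 and 3.41 without DOX replicate 1) and Gzmb (4.67 without PBS replicate 1). Bche, Saa2 and Saa1 were measured in libraries whose hepatocyte marker score on the log2 scale was 2.38, 0.36 and 3.80 above the PBS mean in DOX replicates 1, 2 and 3. Each of these genes was highest in DOX replicate 3 and lowest in DOX replicate 2, as was that score. Arg1, a member of the hepatocyte list, did not follow that order, at 75.6, 26.2 and 27.6 CPM in DOX replicates 1, 2 and 3.

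The 8 genes that fell most by the same rule changed less. Ptx3, a pentraxin of innate immunity, was 3.99-fold lower in DOX, at 10.5 ± 4.68 CPM in PBS and 2.62 ± 0.835 CPM in DOX (log2 fold change -1.99, SE 0.41, edgeR adjusted p = 0.0408). The protocadherin gene Pcdh12 was 3.50-fold lower (edgeR adjusted p = 0.0265) and the matrix metalloproteinase gene Mmp10 3.20-fold lower (edgeR adjusted p = 0.0415). Star, which encodes a mitochondrial cholesterol transfer protein, fell from 107 ± 1.77 to 37.3 ± 13.5 CPM (log2 fold change -1.52, SE 0.23, edgeR adjusted p = 0.0256). Slc26a10, Aloxe3, Mir17hg (the host transcript of a microRNA cluster) and Spaca6 had log2 fold changes of -1.58, -1.54, -1.29 and -1.27, all past the edgeR threshold.

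**Figure D2:**
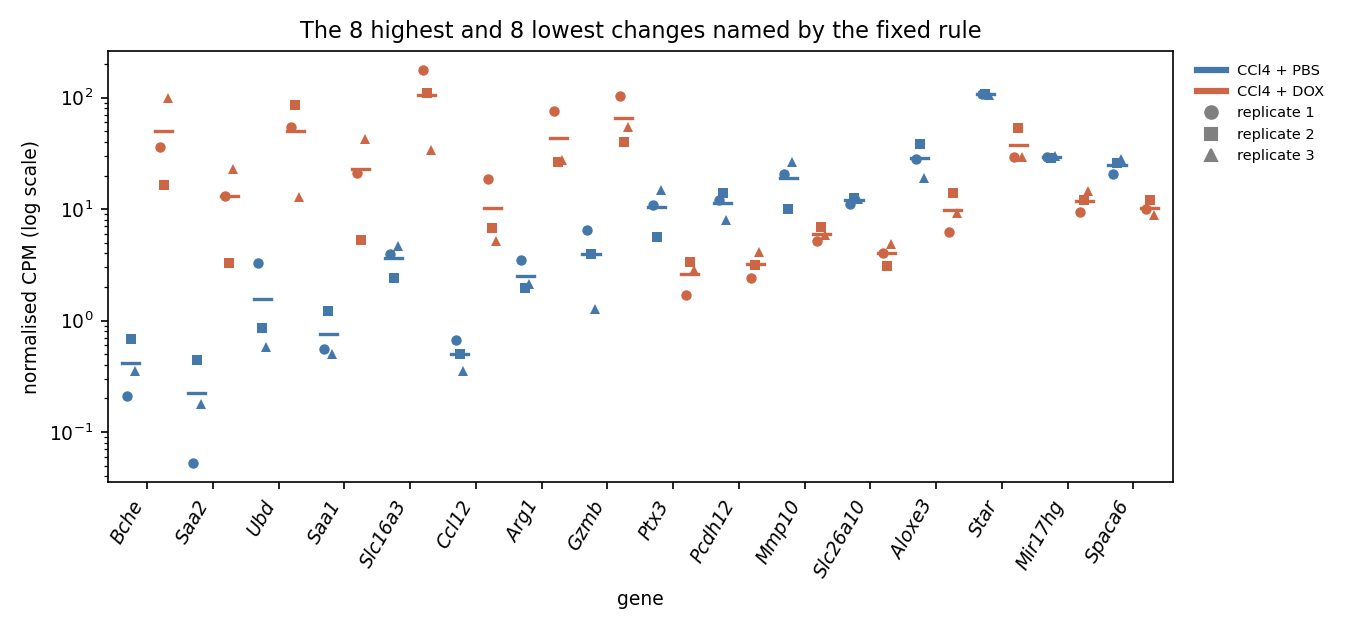
Normalised CPM on a log scale for the 8 genes with the highest and the 8 with the lowest log2 fold changes taken by the naming rule, with each point a library and each bar the mean of 3. Slc16a3 rose from a mean of 3.68 to 106 CPM, and Star fell from 107 to 37.3 CPM.

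The core activation panel of 9 genes also holds Lrat, a member of the list of quiescent stellate cell genes. None of the 9 genes was called by edgeR, over all genes or when adjusted over the list alone. Of these 1 had an unadjusted p under 0.05, limma-voom called 0, and DESeq2 called 1, Acta2, as lower (adjusted p = 0.00724). Acta2, the smooth muscle actin of myofibroblasts, had 39.3 ± 14.8 CPM in PBS and 17.9 ± 4.79 CPM in DOX (log2 fold change -1.13, SE 0.32, edgeR adjusted p = 0.0797). Col1a1 and Col1a2, the chains of type I collagen, had log2 fold changes of -0.10 (SE 0.40, edgeR adjusted p = 0.897) and 0.11 (SE 0.43, edgeR adjusted p = 0.893), with 149 ± 86.0 and 169 ± 99.7 CPM in PBS. Col3a1 had a log2 fold change of -0.15, Timp1, an inhibitor of metalloproteinases, 0.84, Tgfb1 0.21, the platelet-derived growth factor receptor gene Pdgfrb -0.76, Des, which encodes desmin, -0.24, and Lrat, the retinol-esterifying enzyme of stellate cells, 0.27, with edgeR adjusted p between 0.219 and 0.831. Timp1 was at 0.18 without DOX replicate 2, which held 131 CPM against 51.4 and 43.8 CPM in DOX replicates 1 and 3, and Tgfb1 was between 0.10 and 0.29 with each library left out. Of 36 tested genes of quiescent stellate cells, edgeR (also when adjusted over the list alone) and limma-voom called 0 and DESeq2 2, with 2 at an unadjusted p under 0.05 and a median log2 fold change of 0.07 (-0.06 by library totals alone). In the PBS libraries Lrat had 2.00 CPM and Des 12.7 CPM, beside 2614 CPM of the endothelial gene Cdh5 and 1270 CPM of the macrophage gene Mpeg1. The size of this gap depends on the genes chosen, as Cdh5 and Mpeg1 are among the most abundant of their lists. Summed over tested members, which lists share in part, the quiescent stellate list had 3534 CPM in PBS, the endothelial list 9601 and the macrophage list 10266. With the macrophage covariate, chosen after the data were seen, the log2 fold change was -0.0027 for Acta2 and 0.60 for Col1a1. That score overlapped with the groups (r = 0.886 over the 6 libraries), so the fit cannot tell a macrophage share from a group effect.

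Of 27 contractile genes, Csrp1, a cytoskeletal LIM protein gene named after its value was seen, was the only member called by edgeR and by limma-voom and rose 2.36-fold, while DESeq2 called 5 higher and 4 lower. Adjusted over the list alone, 5 contractile genes were higher and 5 lower, and 19 of the 27 had a negative log2 fold change. Tagln, which encodes transgelin, had 48.4 ± 22.8 CPM in PBS and 17.0 ± 8.13 CPM in DOX (edgeR adjusted p = 0.0958, DESeq2 adjusted p = 0.00683). Of 32 fibrillar collagen and matrix genes, Col12a1 fell (log2 fold change -1.24, SE 0.28, edgeR adjusted p = 0.0480), a call that was lost with RLE factors, and 0 passed when adjusted over the list alone, while DESeq2 called 4 lower and limma-voom 0. The matricellular genes Thbs1 and Tnc had log2 fold changes of -1.24 and -1.32 with edgeR adjusted p of 0.0732 and 0.0856 and DESeq2 adjusted p of 0.00272 and 0.00563. Of 14 basement membrane genes, Hspg2, which encodes perlecan, fell from 576 ± 55.4 to 322 ± 67.4 CPM (edgeR adjusted p = 0.0365), and 3 members were lower when adjusted over the list alone. The collagenase gene Mmp13 rose 2.71-fold from 325 to 880 CPM (edgeR adjusted p = 0.0281), and with Mmp10 it made up the 2 of 28 matrix degradation genes that passed, with 1 higher and 1 lower when adjusted over the list alone. Tgm2, a protein-crosslinking transglutaminase gene, rose 1.94-fold and was the 1 of 28 collagen processing genes called, with 0 when adjusted over the list alone, 5 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom.

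Smad6 and Smad7, the inhibitory SMAD genes, were 1.65-fold and 1.80-fold lower in DOX (edgeR adjusted p = 0.0277 and 0.0467), and Id1, named after its value was seen, rose 1.87-fold. These were the 3 called of 33 TGF-beta genes, with 2 higher and 7 lower when adjusted over the list alone. Wwtr1, which encodes the transcriptional coactivator TAZ, fell from 782 ± 54.8 to 557 ± 36.9 CPM (log2 fold change -0.49, SE 0.11, edgeR adjusted p = 0.0451). Asap1 fell with it, and the pair made up the 2 called of 23 YAP and TEAD genes, with 1 higher and 7 lower when adjusted over the list alone. The cell cycle inhibitor genes Cdkn2a and Cdkn2b, both markers of senescence, were 2.23-fold and 2.29-fold lower (edgeR adjusted p = 0.0334 and 0.0240). In the same list of 24 p53 and senescence genes Zmat3 fell, while Pmaip1 and Btg2, both named after their values were seen, rose. Adjusted over the list alone, 3 were higher and 5 lower. In the same libraries the endothelial marker score on the log2 scale was -0.11, -0.23 and -0.28 in DOX replicates 1, 2 and 3. It was -0.15, 0.0076 and 0.14 in PBS replicates 1, 2 and 3. The macrophage score was 1.47, 0.67 and 0.97 in DOX against -0.17, 0.28 and -0.11 in PBS.

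Of 38 chemokine and cytokine genes, 10 rose and 0 fell, and 14 rose when adjusted over the list alone, with a camera adjusted p of 0.450 with an estimated correlation. Il1b, which encodes the cytokine interleukin 1 beta, rose 6.04-fold from 95.2 ± 22.6 to 575 ± 161 CPM (log2 fold change 2.60, SE 0.26, edgeR adjusted p = 0.0200). Il10 rose 5.84-fold, Il18 5.30-fold and Il1a 3.02-fold (edgeR adjusted p = 0.0159, 0.0200 and 0.0200). Of 28 NF-kB response genes, 5 rose, namely Irf1, Sod2, Nfkbie, Rel and Birc2 (the last named after its value was seen), and 9 rose when adjusted over the list alone (camera adjusted p = 0.482 with an estimated correlation). Irf1, an interferon-regulated transcription factor gene, rose 3.31-fold. Of 23 complement genes, 6 rose, and 10 when adjusted over the list alone (camera adjusted p = 0.450 with an estimated correlation). Cfb, which encodes complement factor B, rose from 358 ± 46.1 to 1181 ± 291 CPM (edgeR adjusted p = 0.0206), C5ar1 rose 2.96-fold and C2 2.35-fold. Macrophage transcripts moved with these groups, with a marker score on the log2 scale of 1.47, 0.67 and 0.97 in DOX replicates 1, 2 and 3 against -0.17, 0.28 and -0.11 in PBS. The genes C1qa, C1qb and C1qc are in both the complement and the macrophage list, so those lists move together in part by construction.

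All 40 tested members of the interferon list had a positive log2 fold change (39 by library totals alone), with a median of 0.64. Of these 7 passed over all genes and 22 when adjusted over the list alone, and as a set the list had a camera adjusted p of 0.482 with an estimated correlation. Without DOX replicate 3, a setting chosen after the data were seen, 11 members passed over all genes. Igtp, Gbp6, Iigp1 and Gbp2, all interferon-inducible GTPase genes, rose 3.57-fold, 3.45-fold, 3.25-fold and 3.18-fold (edgeR adjusted p between 0.0365 and 0.0418), and Gbp2 reached 2719 ± 991 CPM. These families hold close paralogs whose reads may be shared. Of 10 genes of MHC class II presentation, 3 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.450 with an estimated correlation). Ciita, the class II transactivator gene, rose 3.57-fold, H2-DMb1 2.94-fold and H2-DMa 2.90-fold (edgeR adjusted p = 0.0480, 0.0206 and 0.0281). In the same libraries the marker score of monocytes and dendritic cells on the log2 scale was 1.16, 1.08 and 1.10 in DOX replicates 1, 2 and 3 against 0.41, 0.19 and -0.60 in PBS, and the macrophage score was 1.47, 0.67 and 0.97 against -0.17, 0.28 and -0.11.

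Glycolysis and hypoxia genes had the largest share of called members of the lists fixed beforehand that had 20 or more tested genes, with 12 of 27 higher and 0 lower, and 18 higher and 1 lower when adjusted over the list alone. Its camera adjusted p was 0.450 with an estimated correlation. Beside Slc16a3, the mitophagy receptor gene Bnip3 rose from 5.75 ± 1.29 to 63.4 ± 36.6 CPM (log2 fold change 3.46, SE 0.50, edgeR adjusted p = 0.0240). Pdk1, a kinase that restrains pyruvate dehydrogenase, rose 4.88-fold, and Egln3, an oxygen-dependent prolyl hydroxylase gene, 4.51-fold (edgeR adjusted p = 0.0206 and 0.0240). Without DOX replicate 3, 20 members were higher, a setting chosen after the data were seen. Of 41 cell cycle genes, Ccnd1, Nusap1, Top2a and Mki67 rose (2.89-fold, 3.25-fold, 2.50-fold and 1.87-fold), and 20 rose when adjusted over the list alone (camera adjusted p = 0.450 with an estimated correlation). Of 28 immediate early genes 6 rose, among them Dusp2 (5.19-fold), Nr4a3 (2.41-fold), Zfp36 (2.07-fold) and Fos (1.95-fold), and 11 when adjusted over the list alone (camera adjusted p = 0.482 with an estimated correlation). Gsr and Sod2 rose among 24 oxidative stress genes, and 7 members when adjusted over the list alone (camera adjusted p = 0.450 with an estimated correlation). In the same DOX replicates 1, 2 and 3 the T cell and NK cell score was 2.40, 1.48 and 2.15 on the log2 scale (0.71, 0.11 and -0.82 in PBS), the macrophage score 1.47, 0.67 and 0.97 (-0.17, 0.28 and -0.11 in PBS) and the hepatocyte score 2.38, 0.36 and 3.80 (-0.85, 0.37 and 0.48 in PBS).

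**Figure D3:**
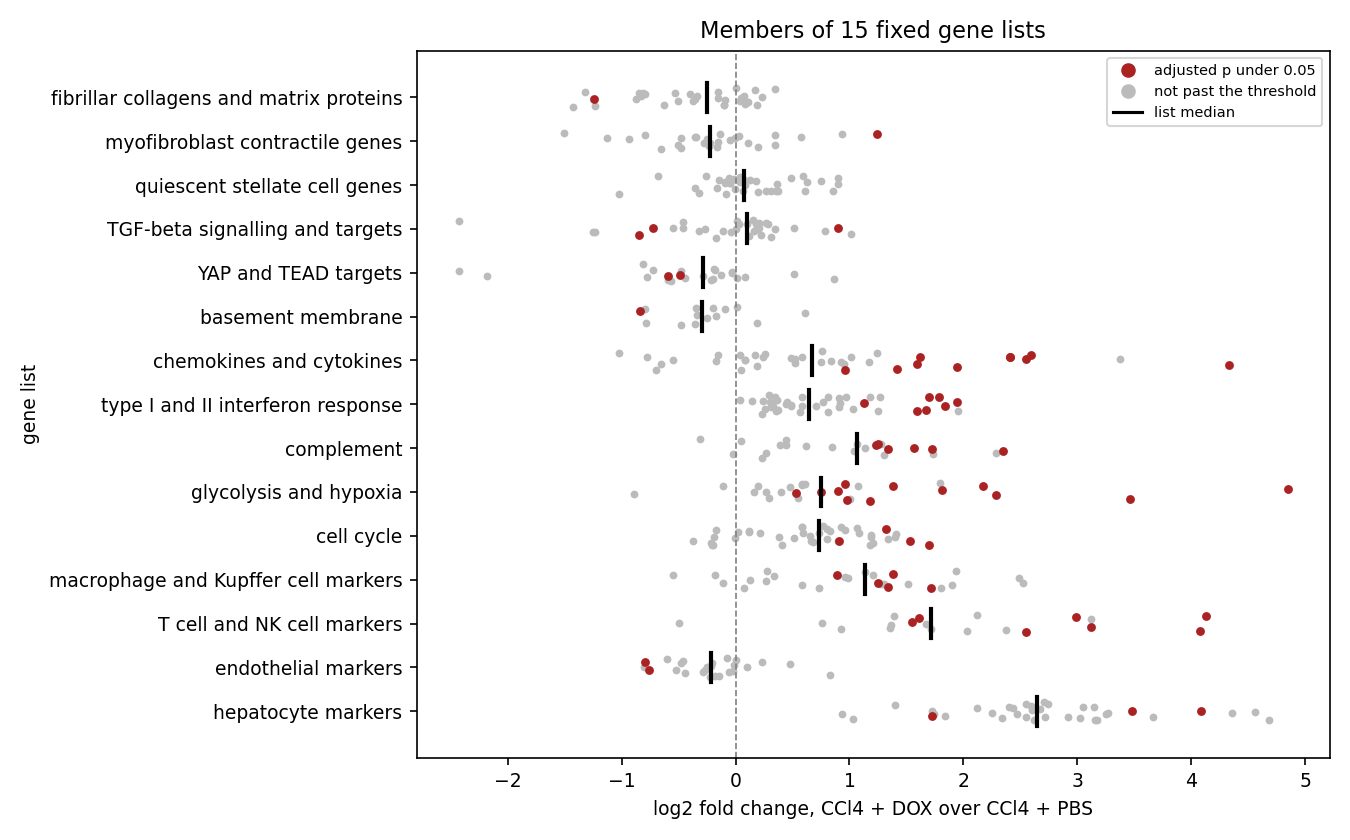
Log2 fold changes of DOX over PBS for the tested members of 15 gene lists fixed before the data were examined, with each point a gene, red where the edgeR adjusted p was under 0.05, and each bar a list median. In the glycolysis and hypoxia list 12 of 27 members were called higher, and in the quiescent stellate cell list 0 of 36 were called.

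Transcripts of other liver cell types were present in both groups, and some leukocyte markers passed the test as higher in DOX. Cdh5 and Pecam1, junction genes of endothelial cells, had 2614 ± 228 and 847 ± 41.6 CPM in PBS and 2357 ± 308 and 724 ± 37.4 CPM in DOX, and the macrophage genes Mpeg1 and Lgmn had 1270 and 1434 CPM in PBS and 2106 and 1739 CPM in DOX. None of these 4 genes passed in edgeR or limma-voom, and DESeq2 called Mpeg1 higher (adjusted p = 0.0134). Lrat, by comparison, had 2.00 ± 1.32 CPM in PBS, and the quiescent stellate genes Abcc9 and Rgs5 had 66.9 and 48.9 CPM. Of 27 macrophage and Kupffer cell markers 5 rose, namely Aif1 (3.29-fold), Cd14 (2.61-fold), C1qc (2.53-fold, named after its value was seen), C1qb (2.38-fold) and Fcer1g (1.85-fold), and 16 when adjusted over the list alone. Without DOX replicate 3, 2 members of the whole list were called higher. Of 16 monocyte and dendritic cell markers 5 rose, namely Siglech (6.45-fold), Ccr9 (5.83-fold), Flt3 (4.32-fold), Plac8 (3.01-fold) and Itgam (2.08-fold, named after its value was seen), and 6 when adjusted over the list alone. Of 19 T cell and NK cell markers 7 rose, among them Nkg7 (7.91-fold, to 1.88 CPM), Xcl1 (5.86-fold) and Thy1 (3.06-fold), and 16 when adjusted over the list alone. Jchain, the joining chain of secreted immunoglobulins, rose 17.5-fold to 8.51 CPM (edgeR adjusted p = 0.0200) and was the 1 of 7 B cell and plasma cell markers called, over all genes and when adjusted over the list alone. Of 11 neutrophil markers 4 rose, namely S100a8 (6.30-fold), S100a9 (6.24-fold), Csf3r (2.94-fold) and Mpo, and 5 when adjusted over the list alone. Mpo went from 0.00884 to 1.04 CPM, where the PBS value was 1 read in PBS replicate 1. Its log2 fold change of 6.44 is therefore loosely fixed and reached 8.27 with a library left out. With an estimated correlation the camera adjusted p was 0.482 for the B cell list and 0.450 for each of the other 4 leukocyte lists.

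All 36 tested hepatocyte markers had a positive log2 fold change, with a median of 2.64, which was 1.37 without DOX replicate 3. Of these 3 passed over all genes, namely Arg1, Serpina3k (11.1-fold, of a family with close paralogs, with a log2 fold change of 3.48 that was 2.73 without DOX replicate 3) and Hp, which encodes haptoglobin (3.30-fold), and 31 when adjusted over the list alone (camera adjusted p = 0.482 with an estimated correlation). Alb itself had 153 ± 62.6 CPM in PBS and 775 ± 949 CPM in DOX (edgeR adjusted p = 0.158). Of 25 endothelial markers, the receptor genes Tek and Ptprb fell 1.74-fold and 1.70-fold (edgeR adjusted p = 0.0311 and 0.0240), and 1 was higher and 6 lower when adjusted over the list alone. Epcam was the 1 of 16 cholangiocyte markers called and rose 3.03-fold, with 1 higher when adjusted over the list alone. Thy1 was the 1 of 23 portal fibroblast and mesothelial markers called, with 1 higher and 2 lower when adjusted over the list alone.

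As sets, 23 of the 43 lists tested passed camera with a preset inter-gene correlation of 0.01, with 18 higher and 5 lower in DOX. Glycolysis and hypoxia and the interferon list had the lowest values (camera adjusted p = 6.18e-13 for each). No list passed with an estimated correlation, where the smallest adjusted p was 0.450 and 4 lists had an unadjusted p under 0.05. The directional fry test passed 3, the cholinergic, cell cycle and neutrophil lists. The cholinergic list holds Bche, the manipulated gene, at a log2 fold change of 6.91. It was not tested without Bche, so its set results rest in part on the manipulation itself. The lower lists were YAP and TEAD targets, fibrillar collagens and matrix proteins, basement membrane, endothelial markers and the integrated stress response, with adjusted p between 0.482 and 0.922 with an estimated correlation. Without DOX replicate 3, the fibrillar collagen, basement membrane and endothelial lists lost the call (camera adjusted p = 0.212, 0.181 and 0.0726, preset correlation). The YAP and TEAD and integrated stress response lists kept it (camera adjusted p = 3.48e-05 and 0.00993).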

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

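The covariate and length settings and the list counts without DOX replicate 3 were chosen after the data were seen. The other settings were chosen before, and the cause of each difference was not tested unless stated. All 926 called genes kept their direction wherever they were tested, except 1 higher gene with the macrophage covariate. The number called was 926 with RLE factors, 988 with upper-quartile factors, 862 with limma-voom, 881 with the robust fit, 1132 with no low-count filter, 893 with the length trend removed and 949 without genes of other cell types' lists. It was 2629 with DESeq2 (923 of the 926 among them), and 484 at an absolute log2 fold change of at least 1, by construction. DESeq2 gave 24.7% false calls on simulated counts, where only 100 genes were changed by each of 2 fold sizes. That share depends on how many genes truly change, so it cannot be carried over to the 2629. Leaving out each library gave 0 (PBS replicates 2 and 3) to 1090 genes (DOX replicate 3) in fits with 5 libraries. With the macrophage covariate edgeR called 0 genes (652 at an unadjusted p under 0.05) and with the hepatocyte covariate 1 (2533). Whether replicate numbers pair the libraries could not be settled from the values. Same-numbered PBS and DOX libraries had correlations of deviations of 0.09, -0.11 and 0.23, the last being the highest of all pairs. PBS replicate 1 correlated best with DOX replicate 2. With 3 libraries per group these correlations are not independent of each other. With the replicate block 781 genes were called, 587 of them among the 926, 24 lists passed camera and Bche had a log2 fold change of 6.61.

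Lists past camera numbered 23, against 0 with an estimated correlation (4 at an unadjusted p under 0.05), 3 by fry, 15 with the hepatocyte covariate, and 20 to 26 with each library left out. Bche had a log2 fold change of 6.66 in limma-voom and 5.92 with the macrophage covariate, both short of the threshold, 2.74 on log2(FPKM + 1), where the pseudocount lowers it by construction, and 5.96 to 7.45 with each library left out. Of the named genes, 96 were called, 95 of them kept their direction in every setting and 0 stayed past the threshold in every setting. By library totals alone the calls of Slc44a1, Mki67, Rcan1, Id1 and Epcam were lost, with RLE factors those of Col12a1 and Igf1r, and with upper-quartile factors that of Rcan1. The exception in direction was C1qc, at -0.11 with the macrophage covariate, whose score holds C1qc itself. Of the 19 not called, 10 changed direction in some setting. With the macrophage covariate the log2 fold change was 0.19 for Ache, 0.60 for Col1a1, 0.36 for Col3a1, -0.15 for Tgfb1, 0.24 for Pdgfrb, 0.21 for Des and -0.027 for Mpeg1. With the hepatocyte covariate it was 0.081 for Col1a1, -0.071 for Lrat and -0.83 for Alb. Mpeg1 is itself in the macrophage score and Alb in the hepatocyte score, so their shifts follow in part by construction. The macrophage score also overlapped with the groups (r = 0.886 over the 6 libraries). For Col1a1 the log2 fold change was 0.0048 in limma-voom and 0.022 with the replicate block, and for Col1a2 -0.033 by library totals. Over the libraries left out, Ache ranged from -0.52 to 0.021, Col1a1 from -0.36 to 0.48, Col1a2 from -0.19 to 0.70, Col3a1 from -0.41 to 0.45, Des from -0.50 to 0.12 and Lrat from -0.018 to 0.96. Genes under about 0.5 CPM, such as Ache and Chrm4, rest on few reads, which limits what their comparison can show.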

Other observations

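The tests of chance regrouping were chosen before their results were seen, and the other tests in this part, on Bche, on the inflammatory and glycolytic genes, on gene length and on the integrated stress response, were chosen after, with the bound used for the macrophage share set once its value was known.

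Of 28 integrated stress response genes, Slc7a1, a cationic amino acid transporter gene, fell 1.71-fold (edgeR adjusted p = 0.0415), and 10 members were lower and 1 higher when adjusted over the list alone, with a camera adjusted p of 1.94e-04 and an adjusted p of 0.578 with an estimated correlation. DESeq2 called 9 of these genes lower, and 12 were lower and 2 higher at an unadjusted p under 0.05. In each of the lists of mitochondrially encoded transcripts (13 tested), nuclear-encoded oxidative phosphorylation (61), mitochondrial ribosome (54), cytosolic ribosomal proteins (68), cholesterol synthesis (24) and fatty acid synthesis and storage (20), edgeR called 0 members, limma-voom 0 and DESeq2 1 or fewer. At an unadjusted p under 0.05 they held 1, 8, 4, 3, 3 and 4 members. As a set, the oxidative phosphorylation list was higher by camera with the preset correlation (adjusted p = 0.0395). In it 51 of 61 members had a positive log2 fold change, and 32 by library totals alone. The camera call was lost without DOX replicate 3 (camera adjusted p = 0.549) and with an estimated correlation (camera adjusted p = 0.922). The unfolded protein response list of 22 genes had 0 calls by edgeR and limma-voom, 1 by DESeq2 and 3 at an unadjusted p under 0.05, and the 9 tested vascular smooth muscle markers had 0 by edgeR and limma-voom, 3 lower by DESeq2, 3 lower when adjusted over the list alone and 3 at an unadjusted p under 0.05. Of the erythroid and platelet list 4 members were tested, with 0 calls by edgeR, DESeq2 and limma-voom and 0 at an unadjusted p under 0.05.

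In the remaining lists 1 or 2 members were called. Of 34 genes of Gq and calcium signalling, Rcan1, a calcineurin regulator gene, rose 1.28-fold and Camk1 fell 1.32-fold, but 0 passed when adjusted over the list alone (6 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom), and Rcan1 lost its call in 16 of 20 alternative settings and Camk1 in 10. Of 28 Wnt and hedgehog genes, the receptor gene Fzd7 rose 2.22-fold and Nkd2, a Wnt antagonist gene, fell 3.17-fold, with 1 higher and 1 lower when adjusted over the list alone. Of 25 growth factor receptor genes Igf1r fell 1.41-fold, and 0 passed when adjusted over the list alone (4 at an unadjusted p under 0.05, 4 by DESeq2 and 1 by limma-voom). Of 25 retinoid genes Lipe, a hormone-sensitive lipase gene, rose 2.19-fold and the retinoic acid receptor gene Rara fell 1.32-fold, with 1 higher and 1 lower when adjusted over the list alone, and of 16 heat shock genes Hsph1 fell 1.46-fold, with 1 lower when adjusted over the list alone. All had an edgeR adjusted p between 0.0314 and 0.0489. Rcan1, Fzd7, Rara and Hsph1 were named after their values were seen.

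The 926 genes called between DOX and PBS had no match in the 9 other splits of the 6 libraries into 3 and 3, where the highest count was 0. The real split was thus 1 of 10 with as many genes, and 10 splits cannot give a share under 0.05. Each other split puts PBS and DOX libraries together, so any group difference adds to the spread there and lowers the calls. For the lists past camera, 3 of 10 splits had as many as the real 23, and the highest of the others had 24. The lowest of the others had 13, so camera with the preset correlation called many lists under every grouping.

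Bche transcripts in libraries of stellate cells invite a closer look, because the manipulation is described for hepatocytes. More hepatocyte RNA at the PBS level of Bche is argued against by the ratio of Bche to Alb, whose lowest DOX value was 13.05 times its highest PBS value. Bche made by stellate cells at an even level per cell is argued against by its log2 ratio of 2.60 between DOX replicates 3 and 2, since 0 percent of 36 quiescent stellate cell genes had a ratio as high and the highest was 1.77. Bche-rich hepatocyte RNA carried into the libraries, as free RNA or as cells, may account for it, since 2.60 lies within the central 95% of the ratios of 36 hepatocyte markers (0.046 to 6.22, median 3.36), a wide range. Stellate cells that made Bche unevenly between libraries stay open and were not tested.

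The 40 chemokine, NF-kB, interferon, complement and glycolysis genes taken here were the list members that edgeR called higher in these same data. Their median fold is therefore higher than that of the whole lists, whose median log2 fold changes were between 0.50 and 1.07 over all tested members. Of the 40, 2 are also in the macrophage list. Their rise came with higher macrophage markers. RNA of hepatocytes in DOX replicate 3 alone is argued against as the whole of it, since the median log2 fold change was 1.72 without that library and 1.61 with it. Over all tested members, the list medians without that library were between 0.59 and 0.95. Hepatocyte RNA in the other DOX libraries was not tested by this. The hepatocyte score was 2.38 in DOX replicate 1 and 0.36 in DOX replicate 2. With that score as a covariate, edgeR called 1 gene of all those tested, Bche. A larger share of macrophages with unchanged expression could raise these genes and cannot be told apart from a response of the cells. With the macrophage score as a covariate their median log2 fold change was 1.23 (quartiles 0.70 and 1.79, median SE 0.41) in place of 1.61 (1.12 and 2.00, median SE 0.25), no call remained and 18 of the 40 had an unadjusted p under 0.05; the fold was smaller and the SE larger, and no test told a smaller effect from the overlap of the score with the groups (r = 0.886 over the 6 libraries). The 40 genes and the macrophage markers differed in the same direction between DOX replicates 1 and 2 (median log2 differences of 0.30 and 0.96) and 1 and 3 (0.71 and 0.55). They differed in opposite directions between DOX replicates 3 and 2 (-0.43 and 0.24), which leaves the macrophage share open. The effect of hepatocyte butyrylcholinesterase stays open as an untested biological explanation. An action of DOX itself stays open too, since no group with DOX and without the introduced gene was analysed here.

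Genes that fell were long, with a median length of 5911 nt against 2995 nt for genes that rose and 3584 nt for the other genes tested. With each library's length trend removed, the median log2 fold change of the genes that fell was -0.626, against -0.633 before. Of the 294, 237 were still called lower, so most of these calls did not need the trend. Removal also moved the median of all tested genes from -0.013 to -0.068. The genes were picked for being lower, and the lengths of genes called after removal were not measured. The fit therefore cannot say why the genes that fell were long. The rank correlation of length and log2 fold change over the 14439 genes, which are not independent replicates, was -0.18. Differences in RNA integrity were not tested.

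A direct action of the DOX treatment on mitochondrial translation could raise the integrated stress response apart from the introduced gene. The mean score of that list was -0.34 in DOX relative to PBS, between -0.55 and -0.08 in DOX and between -0.14 and 0.16 in PBS, so no rise was seen, but the ranges overlap and no group with DOX and without the introduced gene was analysed here.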
